A study of Homo sapiens with 6 samples.

How the data were processed

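Poly(A)-selected RNA of MDA-MB-231 cells was sequenced in 6 libraries, 3 of cells with a doxycycline-inducible hairpin against HOTAIR (shHOTAIR) and 3 of cells with an inducible scrambled hairpin (shCtrl), all kept in 1 µg/ml doxycycline for 96 h per the labels' protocols. The libraries were grouped by the hairpin named in their labels, which matched the column names. Per the labels' protocols, RNA was selected with a NEBNext poly(A) module and libraries were made with a PrepX mRNA kit on an Apollo 324 instrument. Per the submitters' processing notes, TopHat2 2.0.13, DESeq and the genome build GRCh38 were used, with the role and order of the programs not stated. The authors deposited the FPKM values used here, and the program, annotation, filters and strand setting that made them are not given in the sources used here. The values are not whole fragments times a constant, so no read counts were recovered from them.

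The table held 65198 gene rows, of which 56807 matched GENCODE 29 by Ensembl identifier and 8391 did not. Gene type, symbol, position and longest transcript were taken from GENCODE 29 on GRCh38. Replicates were kept separate. The largest share of tested genes with equal FPKM in any pair of libraries was 0.00628%. The summed FPKM of shCtrl 1, 2 and 3 was 2569505, 2224150 and 2229751, and that of shHOTAIR 1, 2 and 3 was 1820768, 1620978 and 1681609. The relative depth of each library was read from low genes, between 0.001 and 0.1 FPKM, as the commonest ratio of their values to those of shCtrl 1 (tolerance 0.01 on the log2 scale), shared by 333 to 381 of the 1426 to 1634 low genes compared. The values of short RNA genes among the largest changes were divided by these relative values and compared with whole multiples from 1 to 5 of a common unit (tolerance 1%), a test chosen after the data were seen. The absolute depth is not known, so the limit of 3 fragments for HOTAIR rests on 1 step being 1 fragment.

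Values were analysed as log2(FPKM + 1) without further scaling. Genes with a mean of at least 1 FPKM over the 6 libraries were tested, 15934 in all, of which 11587 were protein-coding, 3814 of other types and 533 without a GENCODE match. The groups were compared with limma 3.58.1 in R 4.3.3 (moderated t-test with an intensity trend, no replicate block), with Benjamini-Hochberg adjustment and a threshold of 0.05. HOTAIR was tested in a fit of all 36141 genes above 0 in any library and by an exact two-sided permutation test of its FPKM. Gene lists and chromosomes were tested with camera from limma with a preset inter-gene correlation of 0.01, adjusted over lists and over chromosomes, for sets of at least 2 genes (chromosomes at least 10). Camera with an estimated correlation and fry were run beside it. Members of lists were also counted after adjustment over the list alone. Error values are standard deviations of FPKM over 3 libraries, and SE is that of the log2 change in limma. Preparation and figures used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The tests, the lists, the rule for named genes and the alternatives were fixed before the data were examined.

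The 31 lists covered the HOXC cluster, the HOXD cluster, published HOTAIR-repressed and HOTAIR-induced genes, clustered protocadherins, subunits of PRC2 and LSD1-CoREST, mesenchymal genes, epithelial genes, laminins, integrins and adhesion, collagens and matrix proteins, proteases and inhibitors of invasion, TGF-beta and YAP target genes, inflammatory cytokines and NF-kappaB targets, interferon-stimulated genes, HLA class I and antigen presentation, DNA replication and G1/S, mitosis and G2/M, p53 target genes, hypoxia and glycolysis, cholesterol synthesis, ATF4 and the unfolded protein response, NRF2 target genes, breast stemness genes, mitochondrially encoded genes, nuclear respiratory chain genes, ribosomal proteins, replication-dependent histones, and luminal, fibroblast, leukocyte and endothelial markers. They were written from general knowledge.

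Genes were named by a rule. It took HOTAIR, the 10 largest rises and 10 largest falls among genes past the threshold whose groups did not overlap, the 3 smallest p in each direction, the 3 largest rises and falls among genes with a mean of at least 50 FPKM, up to 4 members of each list with the smallest p, and EZH2, SUZ12, KDM1A, CDH1, VIM and CD44. Because short RNA genes filled many of those places, the largest changes of protein-coding genes were named as well, chosen after their values were seen. Members that went against their list or completed a count of 5 or fewer, and the genes given as examples of segments, were also chosen after their values were seen. Some genes that the rule names are not reported here.

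Alternatives were pseudocounts of 0.1 and 0.01, no filter on low values, a minimum mean of 5 FPKM, rescaling by the median of ratios, quantile normalization, limma without a trend and with robust eBayes, a replicate block, each library left out in turn, an estimated inter-gene correlation and an added limit of 1 on the absolute log2 change. After the data were seen, 2 alternatives were added, protein-coding genes alone and regional centring, in which the median deviation of the 50 nearest protein-coding genes was subtracted from each gene in each library. Segments were runs of at least 20 protein-coding genes whose running median over 51 genes was at least 0.3 in size. Windows were smaller near chromosome ends, and the segments were also computed after the data were seen. The fit was tested on simulated data of 15934 genes, in which 22 of 67 genes changed by a log2 of 0.5, 42 of 67 changed by 1 and 51 of 66 changed by 2 were recovered, with 11 false calls among 126. Copy number could not be measured from these values, and no DNA data were used here.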

Results

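RNA sequencing was carried out on MDA-MB-231, a basal-like human breast cancer cell line, in a pair of derivatives. The shHOTAIR derivative carried a tetracycline-inducible short hairpin RNA against HOTAIR, a long non-coding RNA transcribed from the HOXC locus, and the shCtrl derivative carried an inducible scrambled hairpin. Cells of both kinds were kept in 1 µg/ml doxycycline for 96 h, and 3 independent repeats of each gave 6 libraries. The comparison of shHOTAIR with shCtrl asked how the transcriptome of these cells differed when HOTAIR was targeted. Expression was available as FPKM, a measure of fragments scaled by transcript length and by the depth of the library. Between 27416 and 29392 genes had an FPKM above 0 in a library, and the median FPKM of the protein-coding genes tested lay between 20 and 20.5. The number of fragments per library was not given. The spacing of the values of low genes put the FPKM worth of 1 fragment, relative to shCtrl 1, at 0.812 and 0.839 in shCtrl 2 and 3 and at 0.664, 0.595 and 0.717 in shHOTAIR 1, 2 and 3. A smaller worth means a deeper library, so the shHOTAIR libraries were the deeper ones. Across 11587 protein-coding genes, the correlation of log2 values was 0.990 to 0.994 within groups and 0.966 to 0.973 between groups. The labels name 1 derivative per group, so the p-values compare repeats of 1 derivative with repeats of the other.

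HOTAIR (ENSG00000228630, chromosome 12, 53962308 to 53974956 on GRCh38, minus strand, annotated as an antisense gene) was at the limit of detection in both groups. Its FPKM was listed at 0 in shCtrl 1, 0.0128 in shCtrl 2 and 0.0132 in shCtrl 3. In shHOTAIR 1 and 2 it was listed at 0, and in shHOTAIR 3 it was 0.0113. The 3 values above 0 stood in the ratio of the 1-fragment values of their libraries, so each was taken as 1 fragment, here called 1 step. On that reading the level that 3 fragments would give lay between 0.0281 and 0.0472 FPKM, above every measured value, and covers counting error only. An exact two-sided permutation test of the 6 values gave p = 0.4, where 0.1 is the smallest p that 3 against 3 can give. In the limma fit of all 36141 genes above 0 in any library the adjusted p was 0.786. A difference in HOTAIR was therefore not detectable at this depth, and the loss of the target could not be checked from these libraries. HOXC11, a neighbour in the HOXC cluster, was listed at 0 in all 6 libraries.

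**Figure D1:**
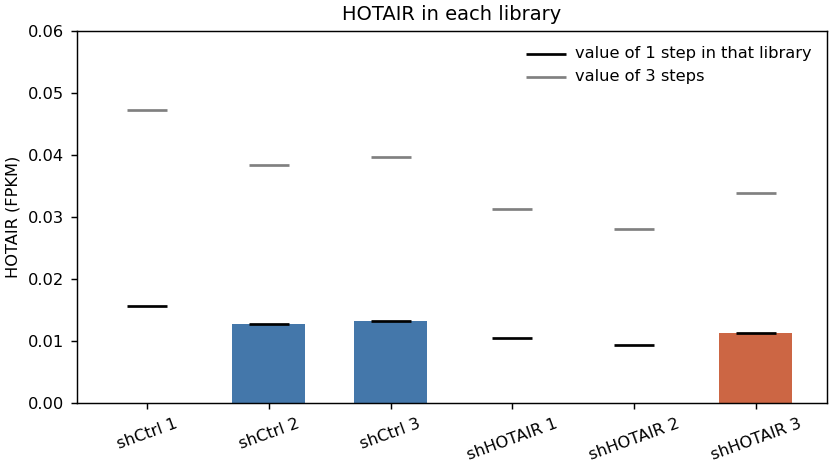
HOTAIR in each library, in FPKM, with shCtrl bars in blue and shHOTAIR bars in orange. Black marks give the value of 1 step in that library and grey marks that of 3 steps, between 0.0281 and 0.0472 FPKM, and no library reached its grey mark.

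Many protein-coding genes differed between the derivatives by far more than the spread of the repeats. ARMCX2 rose from 19.1 ± 1.26 to 271 ± 38.3 FPKM (mean ± SD, n = 3 per group; log2 change 3.75, SE 0.116, limma adjusted p = 0.0002). IL13RA2, a decoy receptor for interleukin 13, rose from 13.3 ± 1.06 to 155 ± 12.5 FPKM (log2 change 3.44, limma adjusted p = 0.000119). CD33, a sialic acid-binding receptor of myeloid cells, rose from 1.22 ± 0.139 to 21 ± 3.34 FPKM, and FHL1, a LIM domain protein, from 48.7 ± 1.27 to 223 ± 6.18 FPKM. In the other direction IL24, a cytokine of the interleukin 10 family, fell from 136 ± 21 to 12.4 ± 5.56 FPKM (log2 change -3.41, SE 0.293, limma adjusted p = 0.00163). The D-type cyclin CCND2 fell from 10.4 ± 0.687 to 0.718 ± 0.214 FPKM, and the mineralocorticoid receptor NR3C2 from 31.9 ± 2.21 to 6.90 ± 0.198 FPKM.

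Among the other protein-coding genes with the largest rises on the log2(FPKM + 1) scale were the neighbouring serpins SERPINB10 (log2 change 2.75) and SERPINB2 (2.71). Their annotated spans overlap, so their reads cannot be fully separated. DCLK2 (2.73), MEST (2.6, from 0.366 to 7.35 FPKM), TINAGL1 (2.59) and the anion transporter SLCO4A1 (2.55) rose as well. CEP97 rose by a log2 change of 2.73, with shHOTAIR values of 89.1, 33.7 and 176 FPKM, and its call was lost without shCtrl 1, shCtrl 2, shCtrl 3 or shHOTAIR 1 (adjusted p up to 0.0824) and with regional centring (0.0577). The largest falls after IL24 on that scale were those of GPAT2, an acyltransferase (log2 change -3.12, from 9.22 to 0.174 FPKM), the sulfotransferase SULT1B1 (-2.91) and PNMA8A (-2.87, from 6.49 to 0.0102 FPKM). The added 1 shrinks changes that reach below 1 FPKM, so by group means these genes fell by larger factors than IL24. The trypsinogen gene PRSS3 (-2.77), which has close paralogs that can share its reads, followed with CHST15 (-2.44), the cathepsin CTSS (-2.39) and AFF3 (-2.27). RGMB, a co-receptor for bone morphogenetic proteins, fell from 235 ± 10.9 to 55.7 ± 2.72 FPKM, and the overlapping antisense gene RGMB-AS1 by a log2 change of -2.81. Whether reads were assigned by strand is not given in the sources used here, so these overlapping genes may share reads. TMEM132D-AS1, another antisense gene, rose from 0.311 ± 0.0514 to 15.1 ± 1.18 FPKM. Falls were also seen in the non-coding AP000233.1, which was listed at 0 in all 3 shHOTAIR libraries, in the pseudogenes AC104333.3 (log2 change -2.92) and GTF2IP7 (-2.87), and in the mitochondrial tRNA gene MT-TD (-2.43).

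In all, 3797 of the 15934 genes tested (23.8%) passed an adjusted p of 0.05 in limma, 1829 higher and 1968 lower in shHOTAIR. The groups did not overlap in 43.0% of the genes tested, where chance gives 10%. Of the changed genes 499 had an absolute log2 change of at least 1, and the median absolute log2 change was 0.54. Among 11587 protein-coding genes, 1595 were higher and 1732 lower. The count was 2508 without shCtrl 1 and 2470 without shCtrl 3. Centring each gene on its 50 nearest protein-coding neighbours, an alternative chosen after seeing the data, gave 2307 genes.

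**Figure D2:**
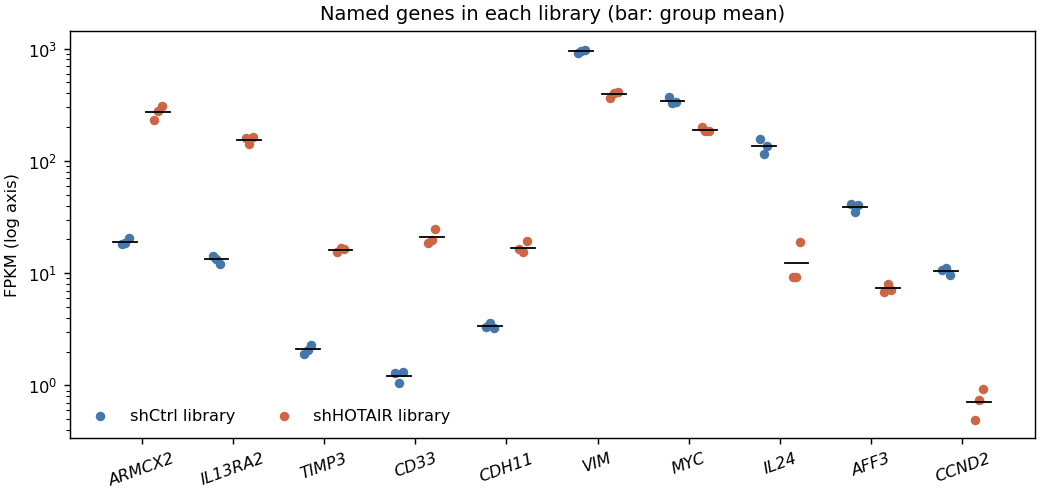
FPKM of 10 named genes in each library, on a log axis, with shCtrl libraries in blue, shHOTAIR libraries in orange and black bars at the group means. The groups do not overlap in any of the 10 genes, and the mean of ARMCX2 is 19.1 FPKM in shCtrl and 271 FPKM in shHOTAIR.

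Short non-coding RNA genes headed the ranking by size of change. Of the 20 genes taken as the 10 largest rises and 10 largest falls, 10 were under 200 bp long. Among genes with a GENCODE match, such short genes were 1.09% of the changed genes and 6.91% of those tested. SNORD27 was listed at or next to 0 in all 3 shCtrl libraries and at 302, 217 and 515 FPKM in shHOTAIR. SNORD42B (96.1, 345 and 104 FPKM in shHOTAIR 1, 2 and 3), RNA5SP474 (58.6, 87.6 and 21.1), RNA5SP450 (11.1, 39.9 and 24.1), RNU6-807P (36.3, 8.13 and 19.6) and MIR6739 (49, 43.9 and 52.9) were listed at 0 in all 3 shCtrl libraries. SNORD72 (52.4, 42.5 and 43.9 FPKM in shCtrl 1, 2 and 3) and RF00019 (10.9, 8.83 and 27.4) were listed at 0 in all 3 shHOTAIR libraries. RNU6-564P was at 30.9, 25.1 and 25.9 FPKM in shCtrl and at 9.18 FPKM in shHOTAIR 2, with 0 in the other 2 shHOTAIR libraries. RF02220 was at 85.6, 48.1 and 63.9 FPKM in shHOTAIR and at 3.2 FPKM in shCtrl 2, with values at or next to 0 in the other 2 shCtrl libraries. The call of RNU6-564P was lost without any library but shHOTAIR 2, with adjusted p up to 0.125, and with regional centring (0.0573). After division by the relative 1-fragment value of each library, the values above 0 of 8 of these 10 genes, all but SNORD27 and RF02220, were whole multiples of a common unit from 1 to 5, within 1%. SNORD72 and MIR6739 stood at equal multiples in 3 libraries, SNORD42B at 1, 4 and 1 and RF00019 at 1, 1 and 3. Of 3719 changed genes of 200 bp or more 4 stood at such multiples. At a mean of at least 1 FPKM longer genes hold more fragments, so few of them could, and the contrast is no evidence by itself. No fold is given against a group listed at 0.

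Few of the genes named in earlier work as linked to HOTAIR passed the test. In the HOXC cluster, which contains the HOTAIR locus, only HOXC6 and HOXC5 of 13 genes reached a mean of 1 FPKM, and their log2 changes of -0.40 and -0.10 did not pass the test. In the HOXD cluster, a reported target region of HOTAIR, the antisense gene HAGLR fell from 22.2 ± 1.10 to 10.5 ± 1.44 FPKM (limma adjusted p = 0.00263), while HOXD4 and HOXD3 had log2 changes of 0.07 and 0.04 that did not pass. The annotated spans of HAGLR and HOXD3 overlap, so reads may be shared between them. The median of the HOXD list was 0.04, its mean was -0.30 and camera put it lower (adjusted p = 0.566, against 0.651 for HOXC). Of the published HOTAIR-repressed genes SRGN, a proteoglycan core protein on chromosome 10, fell by a log2 change of -0.25, and the ephrin receptor EPHA1 (0.33) did not pass. The SRGN call was lost without shCtrl 1 and without shCtrl 3 (adjusted p up to 0.0577), and with regional centring its log2 change was 0.24 (adjusted p = 0.0284). PCDH10, PCDHB5, JAM2, HOXD10 and PGR stayed below a mean of 1 FPKM. The repressed list had a median and a mean of 0.04, and camera put it lower (adjusted p = 0.772). Of the HOTAIR-induced genes LAMB3 (log2 change 0.18) and ABL2 (-0.06) did not pass, and neither did that list (camera adjusted p = 0.346). None of the 4 measured clustered protocadherins passed (camera adjusted p = 0.885; PCDHGC3 had the smallest p).

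Among the 16 subunits of PRC2 and LSD1-CoREST, the chromatin complexes that HOTAIR has been reported to bind, 5 rose and 0 fell, with the same counts adjusted over the list alone. The histone-binding subunits RBBP7 (297 ± 18.8 to 497 ± 22.4 FPKM) and RBBP4 (log2 change 0.47) rose, as did the deacetylase HDAC1 (0.52), MTF2 (0.30) and the demethylase KDM1A (0.22). EZH2, the methyltransferase of PRC2, was at 21.2 ± 0.544 and 22.2 ± 0.941 FPKM (limma adjusted p = 0.441), and SUZ12 at 56.3 ± 6.43 and 61.3 ± 4.19 FPKM (0.413). With camera the list did not pass (adjusted p = 0.132). With regional centring RBBP7 alone of these 5 kept its call, and the log2 change of KDM1A was -0.10 (adjusted p = 0.341). The KDM1A call was also lost without any library but shCtrl 1 (adjusted p up to 0.116), and the RBBP4 call without shCtrl 1, shCtrl 2 or shHOTAIR 2 (up to 0.0638).

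Mesenchymal genes moved in both directions. The cadherin CDH11 rose from 3.38 ± 0.183 to 16.9 ± 2 FPKM, the transcription factor SNAI2 from 9.03 ± 1.18 to 25.3 ± 1.73 FPKM and TAGLN by a log2 change of 0.48. The intermediate filament gene VIM fell from 948 ± 37.1 to 393 ± 27.3 FPKM (log2 change -1.27, limma adjusted p = 0.000616) and fibronectin, FN1, from 199 ± 23.2 to 91.4 ± 8.20 FPKM. ACTA2 (log2 change -0.77) and ZEB1 (-0.38) also fell. VIM, ACTA2 and ZEB1 lie on chromosome 10, where most genes were lower. With regional centring the log2 change of VIM was -0.52 (adjusted p = 0.0114), while ACTA2 (-0.35) and ZEB1 (0.21) no longer passed, with adjusted p of 0.199 and 0.258. ACTA2 lost its call without shCtrl 1, shHOTAIR 2 or shHOTAIR 3 (adjusted p up to 0.0539), and ZEB1 without any library but shHOTAIR 1 (up to 0.138). Of 10 measured members 3 rose and 4 fell (4 and 4 adjusted over the list alone). The median was -0.23, the mean 0.04, and camera put the list lower without passing (adjusted p = 0.995).

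The 8 measured epithelial genes held 5 that rose and 1 that fell, with the same counts adjusted over the list alone, and camera did not pass (adjusted p = 0.0645). Among them the keratins KRT18 (log2 change 0.62) and KRT8 (0.75), the claudin CLDN4 (0.37) and JUP (0.75) rose, and the keratin KRT19 fell (-0.59). The annotated spans of KRT8 and KRT18 overlap, so these genes may share reads. KRT8 lost its call without shCtrl 2, shCtrl 3 or shHOTAIR 2 (adjusted p up to 0.0527), KRT19 without shCtrl 1, shCtrl 3, shHOTAIR 1 or shHOTAIR 2 (0.0796), CLDN4 without any library but shHOTAIR 1 (0.0789) and JUP without shCtrl 1, shCtrl 3, shHOTAIR 2 or shHOTAIR 3 (0.0673). E-cadherin, CDH1, did not exceed 0.114 FPKM in any library. The list passed without shHOTAIR 1 (adjusted p = 0.0369) and with regional centring (0.0128), within a range of 0.0128 to 0.82 over its alternatives. Of 9 measured luminal breast markers 4 rose and 4 fell (4 and 5 adjusted over the list alone). They included MLPH (19.4 ± 1.74 to 54.5 ± 4.23 FPKM), GATA3 (log2 change 0.52), AGR2 (-1.22), XBP1 (-0.40) and FOXA1 (-0.64), and the list did not pass (camera adjusted p = 0.995, median -0.40, mean -0.03, test direction higher). FOXA1 lost its call without any 1 library, with adjusted p of 0.0535 to 0.0849.

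Collagen and matrix genes were higher in shHOTAIR. COL8A1 rose from 14.6 ± 1.57 to 46.4 ± 3.24 FPKM, the collagen VI chain COL6A1 from 2.09 ± 0.575 to 14.2 ± 2.17 FPKM, the basement membrane collagen COL4A1 from 2.38 ± 0.208 to 8.73 ± 1.08 FPKM and the cross-linking enzyme LOXL2 from 27.3 ± 0.536 to 57.4 ± 3.83 FPKM. COL8A1 lies in a higher segment of chromosome 3. With regional centring its log2 change went from 1.61 to 1.16 (limma adjusted p = 0.00209). Of 15 measured members 11 rose and 2 fell (11 and 3 adjusted over the list alone), and the falls were those of FN1 and the lysyl oxidase LOX (19.1 ± 1.44 to 6.64 ± 1.02 FPKM). The median log2 change was 0.96 and camera passed (adjusted p = 0.00116), with adjusted p = 0.535 with an estimated correlation.

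Laminins, integrins and adhesion genes were higher as well. ITGB5 rose from 59.1 ± 1.56 to 96.5 ± 3.71 FPKM, the adhesion molecule ALCAM from 57.4 ± 3.79 to 107 ± 6.56 FPKM, ITGA3 from 217 ± 19.1 to 473 ± 59.6 FPKM and ITGA6 from 176 ± 7.08 to 270 ± 17.3 FPKM. ALCAM lies in a higher segment of chromosome 3. With regional centring its log2 change went from 0.88 to 0.38 (limma adjusted p = 0.0181). Of 20 measured members 9 rose, and the laminin chain LAMB1 fell (log2 change -0.35), a call lost without shCtrl 1, shCtrl 3, shHOTAIR 2 or shHOTAIR 3 (adjusted p up to 0.0815) and with regional centring (0.0761). Adjusted over the list alone the counts were 12 and 3. The hyaluronan receptor CD44 was at 475 ± 26.0 and 480 ± 43.9 FPKM and did not pass. Camera passed for the list (adjusted p = 0.00749, median 0.33), with adjusted p = 0.535 with an estimated correlation.

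Proteases and inhibitors of invasion went both ways, 8 higher and 5 lower of 19, with the same counts adjusted over the list alone. TIMP3, an inhibitor of matrix metalloproteases, rose from 2.10 ± 0.213 to 16.2 ± 0.687 FPKM, and ADAM19 from 3.14 ± 0.268 to 7.22 ± 0.211 FPKM. The proteases ADAMTS1 (48.7 ± 3.66 to 13.7 ± 1.66 FPKM) and ADAM8 (10.0 ± 1.02 to 2.43 ± 0.439 FPKM) fell, as did the collagenase MMP1 (log2 change -0.82), MMP10 (-0.95) and PLAT (-0.58). The MMP1 call was lost without shHOTAIR 2 (adjusted p = 0.0552), and the MMP10 call with regional centring (0.0566). The list did not pass (camera adjusted p = 0.132), though it did with a minimum mean of 5 FPKM (0.047) and with regional centring (0.0228), within a range of 0.0228 to 0.623 over its alternatives. Among 17 TGF-beta and YAP target genes 4 rose, which were ID1 (15.6 ± 1.07 to 45.2 ± 8.29 FPKM), ID3 (log2 change 1.08), AMOTL2 (0.48) and the receptor kinase AXL (0.48). In the same list ANKRD1 (219 ± 12.4 to 93.3 ± 0.878 FPKM, on chromosome 10), ID2 (-0.72) and the receptor TGFBR2 (-0.29) fell. The counts were the same adjusted over the list alone, the list did not pass (camera adjusted p = 0.282), and the ID2 call was lost without any library but shHOTAIR 1 (adjusted p up to 0.0678).

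**Figure D3:**
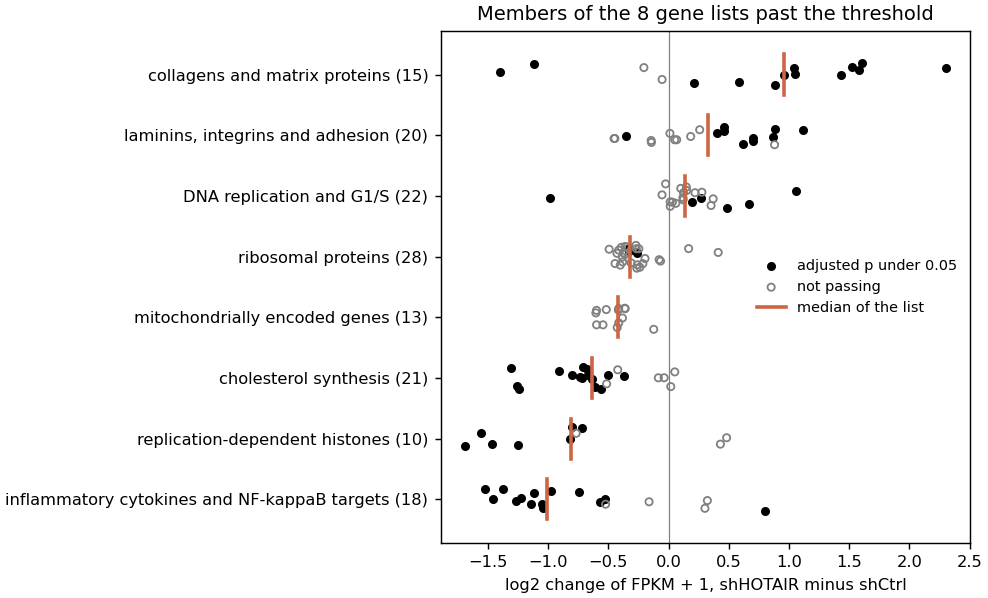
Log2 change of each measured member of the 8 lists past the threshold, shHOTAIR minus shCtrl, on the log2(FPKM + 1) scale, with the number of members in brackets. Filled points passed an adjusted p of 0.05 in limma and orange bars mark the list medians, from -1.01 for the inflammatory list to 0.96 for collagens and matrix proteins.

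Inflammatory genes were lower in shHOTAIR. The NF-kappaB subunit NFKB2 fell from 40.3 ± 2.86 to 14.0 ± 0.443 FPKM, the apoptosis inhibitor BIRC3 from 37.9 ± 2.93 to 12.5 ± 0.433 FPKM, the feedback inhibitor TNFAIP3 from 21.3 ± 1.36 to 9.83 ± 0.420 FPKM and the cytokine IL1A from 31.5 ± 2.90 to 11.5 ± 1.07 FPKM. Of 18 measured members 13 fell and 1 rose, the cytokine IL11 (log2 change 0.80). Adjusted over the list alone 14 fell and 1 rose. The median log2 change was -1.01 and camera passed (adjusted p = 2.97e-05), with adjusted p = 0.535 with an estimated correlation.

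Interferon-stimulated genes were mixed, with 4 of 13 higher and 1 lower (6 and 3 adjusted over the list alone). IFI44 rose from 22.3 ± 4.59 to 44.0 ± 2.21 FPKM, HERC5, IFIT2 and IFIT1 by log2 changes of 0.42, 0.52 and 0.59, and the RNA sensor DDX58 fell from 29.5 ± 1.20 to 17.6 ± 0.493 FPKM. HERC5 lost its call without shCtrl 1, shCtrl 3, shHOTAIR 1 or shHOTAIR 3 (adjusted p up to 0.0653), and IFIT2 and IFIT1 without shCtrl 2, shCtrl 3, shHOTAIR 2 or shHOTAIR 3 (0.0837 and 0.116). With regional centring HERC5 did not pass (log2 change 0.05, adjusted p = 0.729). The list did not pass (camera adjusted p = 0.46). Of 14 genes of HLA class I and antigen presentation 4 fell, in both counts, the peptide transporter genes TAP1 (log2 change -0.60) and TAP2 (-0.67) and the immunoproteasome subunits PSMB8 (-0.78) and PSMB9 (-1.33). The PSMB9 call was lost without shCtrl 3, shHOTAIR 2 or shHOTAIR 3 (adjusted p up to 0.0579), and the list did not pass (camera adjusted p = 0.346). Whether the 4 falls are separate changes or a shift shared by a few neighbouring genes was not tested.

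Genes of cholesterol synthesis were lower in shHOTAIR. INSIG1, a sterol-regulated gene, fell from 36.6 ± 1.49 to 14.7 ± 1.70 FPKM, the isomerase IDI1 from 81.5 ± 2.32 to 49.4 ± 2.54 FPKM, SC5D from 44.6 ± 1.53 to 26.7 ± 1.83 FPKM and MSMO1 from 68.1 ± 0.920 to 44.3 ± 2.48 FPKM. All 21 genes of the list were measured, of which 15 fell and 0 rose (17 and 0 adjusted over the list alone). The median log2 change was -0.64 and camera passed (adjusted p = 3.86e-07), with adjusted p = 0.535 with an estimated correlation. With regional centring the log2 change of IDI1, on chromosome 10, was -0.03 (adjusted p = 0.798).

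Stress and metabolic lists did not pass with camera. Of 24 ATF4 and unfolded protein response genes 9 fell and 2 rose (10 and 2 adjusted over the list alone; camera adjusted p = 0.059). The falls included CHAC1 (5.95 ± 0.187 to 1.99 ± 0.379 FPKM), the transcription factor ATF3 (13.1 ± 1.64 to 4.66 ± 0.886 FPKM) and SLC3A2 (log2 change -0.49), and the rises were SLC7A5 (0.45) and PSPH (0.31). PSPH lost its call without shCtrl 2, shCtrl 3 or shHOTAIR 3 (adjusted p up to 0.0596) and with regional centring (0.875). The list passed without shCtrl 2 (adjusted p = 0.024), without a filter on low values (0.00521) and with regional centring (0.00252), within a range of 0.00252 to 0.628 over its alternatives. Among 24 hypoxia and glycolysis genes 5 rose and 8 fell (7 and 9 adjusted over the list alone; camera adjusted p = 0.566). BNIP3, PFKFB3 and HK1, all on chromosome 10, fell by log2 changes of -0.64, -0.82 and -0.63, and with regional centring none of the 3 passed. ANKRD37 fell by -1.05, and SLC2A1, ADM, EGLN3, PKM and ENO1 rose by 0.47, 0.59, 0.95, 0.44 and 0.37. ADM lost its call without shCtrl 1, shCtrl 2 or shHOTAIR 3 (adjusted p up to 0.0537), and PKM and ENO1 without any library but shHOTAIR 1 (0.108 and 0.135). With regional centring SLC2A1 (adjusted p = 0.0728) and ENO1 (log2 change 0.12, adjusted p = 0.427) did not pass. Among 16 NRF2 target genes 5 rose and 3 fell (5 and 4 adjusted over the list alone; camera adjusted p = 0.885, median -0.11, mean 0.09, test direction higher). The quinone reductase NQO1 rose from 17.3 ± 0.141 to 39.1 ± 2.83 FPKM, and SRXN1, AKR1C3 and GCLM by log2 changes of 0.50, 0.95 and 0.36. With regional centring SRXN1 (adjusted p = 0.273) did not pass.

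In the same list GCLC, TXNRD1 and ME1 fell by log2 changes of -0.31, -0.30 and -0.25. GCLC and TXNRD1 lost their calls without any 1 library (limma adjusted p up to 0.0916 and 0.118), ME1 without any library but shHOTAIR 1 (0.135) and GCLM without any library but shCtrl 2 (0.125). With regional centring none of GCLC, TXNRD1, ME1 and GCLM passed (adjusted p = 0.623, 0.124, 0.0764 and 0.116).

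Genes of DNA replication and the G1/S transition were higher by a small amount. The cyclin CCNE1 rose from 4.24 ± 0.125 to 9.93 ± 0.376 FPKM, the sliding clamp PCNA from 179 ± 6.13 to 286 ± 12.7 FPKM, and CCNE2, MCM3 and RRM2 by log2 changes of 0.49, 0.19 and 0.27. MCM10, on chromosome 10, fell by a log2 change of -0.99, and with regional centring its change was -0.22 (adjusted p = 0.342). Of 22 measured members 5 rose and 1 fell, in both the count over all genes and that adjusted over the list alone. Camera passed (adjusted p = 0.00965, median 0.14), with adjusted p = 0.535 with an estimated correlation. CCNE2 lost its call without shCtrl 1, shCtrl 2, shCtrl 3 or shHOTAIR 3 (adjusted p up to 0.0855), MCM3 without any library but shHOTAIR 1 (0.0838) and RRM2 without any library but shCtrl 2 (0.113).

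The 23 genes of mitosis and G2/M had a median log2 change of -0.01 and a mean of 0.07, and camera put them higher without passing (adjusted p = 0.346). CCNA2 rose from 34.2 ± 1.81 to 53 ± 2.53 FPKM, MAD2L1 and CENPE by log2 changes of 0.45 and 0.31, and the motor protein KIF11 fell by -0.34 (3 and 1 over all genes, 2 and 1 adjusted over the list alone). MAD2L1 lost its call without shCtrl 1, shCtrl 3 or shHOTAIR 3 (adjusted p up to 0.0573), CENPE without any library but shCtrl 2 (0.11) and KIF11 without shCtrl 2, shCtrl 3, shHOTAIR 2 or shHOTAIR 3 (0.0701). With regional centring none of these 3 passed, and CENPE and KIF11 stood at -0.02 and 0.11. Among 16 p53 target genes 5 fell and 0 rose (9 and 2 adjusted over the list alone; camera adjusted p = 0.0645). These were GADD45A (80.7 ± 8.38 to 46.2 ± 2 FPKM), the cell cycle inhibitor CDKN1A (28.7 ± 1.08 to 17.5 ± 1.84 FPKM), the death receptor FAS (log2 change -0.99, on chromosome 10), TP53INP1 (-0.57) and TP53I3 (-0.43). The TP53INP1 call was lost without shCtrl 1 and without shCtrl 3 (adjusted p up to 0.0533), and the TP53I3 call without any 1 library (up to 0.112). With regional centring FAS (log2 change -0.57, adjusted p = 0.0782) and TP53I3 (0.158) did not pass. The p53 list passed without shCtrl 2 (adjusted p = 0.0448), without a filter on low values (0.0228), without a variance trend (0.0497) and with regional centring (0.0128), within a range of 0.0128 to 0.541 over its alternatives.

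Replication-dependent histone genes were lower in shHOTAIR. HIST1H2AC fell from 26.3 ± 2.44 to 7.45 ± 0.121 FPKM, HIST1H2BJ from 80.9 ± 3.50 to 33.4 ± 2.12 FPKM, the linker histone HIST1H1C from 101 ± 8.15 to 33.8 ± 3.87 FPKM and HIST1H2BC from 6.19 ± 1.36 to 1.61 ± 0.621 FPKM. Of 10 measured members 7 fell and 0 rose (8 and 0 adjusted over the list alone). Camera passed (adjusted p = 0.00105, median -0.81), with adjusted p = 0.464 with an estimated correlation. These genes are near-identical copies that can share reads, and most of their transcripts carry no poly(A) tail, so poly(A)-selected libraries see them in part. A shift shared by a few neighbouring histone genes was not tested apart from separate changes.

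Ribosomal protein genes were lower as a set with the preset correlation of camera. RPL7, RPLP0 and RPL27 fell by log2 changes of -0.26, -0.33 and -0.33, and the other 25 of 28 did not pass. Adjusted over the list alone 0 passed. Camera passed (adjusted p = 0.00116, median -0.32), with adjusted p = 0.669 with an estimated correlation. RPLP0 lost its call without shCtrl 1, shCtrl 2, shCtrl 3 or shHOTAIR 2 (adjusted p up to 0.088) and RPL27 without any 1 library (up to 0.12), and RPL7 and RPL27 missed the threshold with regional centring (adjusted p = 0.0702 and 0.0715). Processed pseudogenes of this family can share reads.

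The 13 mitochondrially encoded genes had a median log2 change of -0.42, and none passed the test of single genes, over all genes or adjusted over the list alone, although 7 had an unadjusted limma p below 0.05. MT-ATP6 was at 2141 ± 450 and 1398 ± 196 FPKM (log2 change -0.60, limma adjusted p = 0.0599). Camera passed for the list (adjusted p = 0.00817), with adjusted p = 0.669 with an estimated correlation. The call was lost with quantile normalization (adjusted p = 0.0703) and without shHOTAIR 3 (0.0574). The mitochondrial share of protein-coding FPKM was 8.26, 6.48 and 6.38% in shCtrl 1, 2 and 3 and 6.66, 5.1 and 4.52% in shHOTAIR 1, 2 and 3, so shHOTAIR 1 lay above shCtrl 2 and 3. Mitochondrial tRNA genes, which are very short and therefore high in FPKM, took 57.0 ± 3.19% of the summed FPKM in shCtrl and 42.0 ± 3.15% in shHOTAIR. Of 24 nuclear genes of the respiratory chain 3 rose and 4 fell (3 and 5 adjusted over the list alone; camera adjusted p = 0.346). ATP5F1C and NDUFB8, on chromosome 10, fell by log2 changes of -0.79 and -0.80, and with regional centring neither passed. ATP5F1A (-0.38) and COX5A (-0.18) also fell, and NDUFB3, NDUFS1 and NDUFA1 rose by 0.35, 0.29 and 0.48. COX5A and NDUFS1 lost their calls without any 1 library (limma adjusted p up to 0.0989 and 0.0705), ATP5F1A without any library but shHOTAIR 3 (0.079), NDUFA1 without any library but shHOTAIR 1 (0.0953) and NDUFB3 without shCtrl 2, shCtrl 3, shHOTAIR 2 or shHOTAIR 3 (0.0631). With regional centring COX5A alone of these 5 passed.

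Of 11 measured breast stemness genes 3 rose and 3 fell (5 and 3 adjusted over the list alone; camera adjusted p = 0.488). The Notch target HES1 rose from 4.07 ± 0.248 to 9.78 ± 0.713 FPKM and its ligand JAG1 from 28.9 ± 4 to 54.0 ± 1.52 FPKM, along with ITGA6. MYC fell from 344 ± 23 to 189 ± 10.3 FPKM, BMI1, on chromosome 10, by a log2 change of -0.70 (-0.01 with regional centring) and KLF4 by -0.38. The KLF4 call was lost without shCtrl 1, shCtrl 2, shHOTAIR 1 or shHOTAIR 2 (adjusted p up to 0.0881). Of the fibroblast markers COL1A1 rose from 1.33 ± 0.251 to 3.51 ± 0.282 FPKM, PDGFRB did not pass and the other 8 were below a mean of 1 FPKM. Of the endothelial markers ESAM rose (log2 change 0.33), a call lost without any library but shHOTAIR 1 (adjusted p up to 0.106), and KDR did not pass. Neither list passed (camera adjusted p = 0.349 and 0.15). Of 10 leukocyte markers CD68 alone was measured, at 20.9 ± 0.417 and 17.6 ± 1.67 FPKM (limma adjusted p = 0.0763), so that list was not tested.

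In all, 8 of the 30 lists tested passed with the preset correlation of camera and 0 with an estimated correlation, where the smallest adjusted p was 0.464 and 1 list had an unadjusted p below 0.05. Fry, which asks whether the genes of a list move on balance in 1 direction without setting them against other genes, passed for 16 lists, and for 23 lists when either direction counted. Members named because they went against their list, or because 5 or fewer members moved that way, were chosen after their values were seen.

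Genes shifted together along whole chromosomes. On chromosome 10, where VIM, NFKB2, HK1 and BMI1 lie, 87.8% of 589 genes were lower in shHOTAIR, 335 of them past the threshold against 16 that were higher. The median log2 change was -0.50 (camera adjusted p = 3.06e-25), and the medians in the 3 shHOTAIR libraries were -0.50, -0.51 and -0.49 relative to the shCtrl mean. Genes on chromosome 13, such as COL4A1, were higher by a median of 0.42 (adjusted p = 4.81e-11), those on chromosome X, such as ARMCX2, IL13RA2 and FHL1, by 0.27 (1.04e-10) and those on chromosome 21, such as COL6A1, by 0.25 (9.65e-07). With regional centring the log2 change of COL4A1 went from 1.52 to 0.77 and that of FHL1 from 2.17 to 1.53. Those of ARMCX2, IL13RA2 and COL6A1 became 3.13, 2.80 and 1.92, and all of these genes still passed. Of 24 chromosomes tested 12 passed with camera, 6 higher and 6 lower. The others that passed were chromosomes 1, 15 and 20, higher by 0.16, 0.10 and 0.11, and 6, 11, 18, 19 and the mitochondrial genome, lower by -0.10, -0.10, -0.22, -0.13 and -0.54. With an estimated correlation 8 passed. Chromosome 10 (adjusted p = 0.000592 with an estimated correlation), X (0.00112), 21 (0.0106), 1 (0.00291), 15 (0.00992) and 6 (0.0348) held. Chromosomes 13 (adjusted p = 0.0615 with an estimated correlation), 18 (0.0615), 20 (0.114), 11 (0.139), 19 (0.332) and M (0.402) did not, and chromosomes 14 (0.0348) and 3 (0.0462) passed only with the estimated correlation. Without a filter on low values chromosomes 6, 11 and 15 did not pass (adjusted p = 0.0972, 0.171 and 0.0534), and with a minimum mean of 5 FPKM chromosome 16 did (0.0361).

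Within chromosomes the shifts varied along their length. The limits of segments given here are where a running median crossed 0.3 in size, and no test of a boundary was made. Running medians over 51 neighbouring protein-coding genes, fewer near chromosome ends, were computed after the chromosome result was seen. They reached 0.3 or more in size in 17 segments that held 1626 of 11570 genes. The longest, 3.14 to 134 Mb of chromosome 10, had a median of -0.53 over 435 genes. On chromosome X the segment from 93.7 to 155.9 Mb had a median of 0.64 over 189 genes, and on chromosome 13 that from 45.2 to 114.3 Mb had a median of 0.65 over 117 genes. Chromosome 4 held 3 segments, lower by -0.46 between 0.338 and 25.4 Mb, higher by 0.37 between 75.5 and 165.3 Mb and lower by -0.99 between 183 and 190 Mb. The last of these, of 23 genes near the chromosome end, was set by smaller windows. It contains FAT1, an atypical cadherin, which fell from 50.8 ± 4.29 to 28.6 ± 1.01 FPKM. FAT1 was named after its values were seen.

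**Figure D4:**
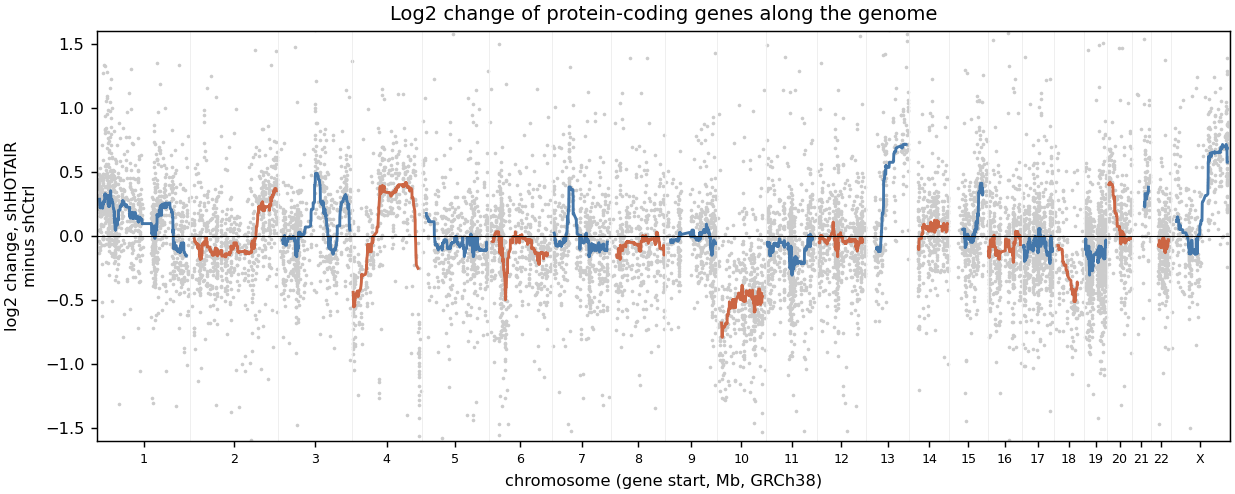
Log2 change of protein-coding genes, shHOTAIR minus shCtrl, by position on GRCh38, with 1 grey point per gene and a line for the running median of 51 genes, coloured by chromosome in turn and drawn where all 51 genes were available. Points beyond -1.6 or 1.6 are not drawn, and the line stays below 0 along chromosome 10 and rises on the long arms of chromosomes 13 and X.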

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

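Regional centring and protein-coding genes alone were chosen after seeing the data. All 3 shCtrl and 3 shHOTAIR libraries gave 3797 changed genes. The count was 2307 with regional centring (1921 shared), 499 with an absolute log2 change of at least 1 as well, where the limit itself removes genes, and 2470 to 3159 without 1 library, where fewer samples are tested. The other settings, apart from the replicate block, gave 3212 to 4176. Of the named genes, 31 lost their calls without a filter on low values, where more genes are tested. With regional centring 33 lost their calls without a change of direction. An estimated correlation left 0 of 8 lists. Across the other settings 7 to 12 lists and 9 to 13 chromosomes passed, and 8 chromosomes with the estimated correlation. No chromosome changed direction. The HOTAIR difference did not pass in any setting. Planned count tests on recovered reads were not run, because the values are not whole reads times a constant.

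With the replicate number as a block 1740 genes passed, 1691 of them shared, and 52 named genes lost their calls. The counts of 8 lists and 12 chromosomes were unmoved. The numbers do not pair the libraries: deviations of same-numbered libraries correlated by -0.0285, 0.0156 and -0.0661 over 9136 genes, and the best partners of shCtrl 1, 2 and 3 were shHOTAIR 3, 2 and 2.

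Directions reversed in these cases, and the cause was not tested. Among genes, with regional centring the log2 changes became KDM1A -0.0992, SRGN 0.238, KIF11 0.108, CENPE -0.0215, ATP5F1A 0.018, ZEB1 0.21, GCLC 0.0609 and NDUFA1 -0.163, and with quantile normalization HOXD3 -0.0101. Without 1 library CD44 ranged from -0.0423 to 0.0866, HOXD4 from -0.00711 to 0.177, ABL2 from -0.122 to 0.00145, PCDHB2 from -0.0582 to 0.0682 and PDGFRB from -0.291 to 0.0863. Among list medians, with regional centring the mesenchymal list was 0.118, mitosis 0.108, hypoxia 0.0613 and NRF2 0.032. Without a filter the interferon list was -0.101 and the luminal list 0.0334, and at 5 FPKM the mesenchymal list was 0.197. Mitosis was 0.00508 when rescaled and 0.000104 with quantile normalization, which gave -0.0101 for the HOXD list. Without 1 library the HOXD list ranged from -0.00711 to 0.0737, the HOTAIR-repressed list from -0.0471 to 0.129, mitosis from -0.03998 to 0.0444 and the stemness list from -0.0161 to 0.0872.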

Other observations

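The tests of copy number, of the loss of HOTAIR, of segment shifts and of short genes were chosen only after the results were seen. In segments that were shifted as a block, 1017 of 1042 genes past the threshold (97.6%) moved with their segment and 25 moved against it. The segments were drawn from these same log2 changes, so a high share is built in. The steroid receptor NR3C2 and TMEM154 fell (TMEM154 from 47.1 ± 3.4 to 17.3 ± 2.31 FPKM, SD, n = 3) within a segment of chromosome 4 that was higher. On chromosome 10, where most genes were lower, the urokinase gene PLAU rose from 135 ± 9.59 to 230 ± 9.51 FPKM, the phosphatase PTPRE from 5.84 ± 0.415 to 14.2 ± 3.02 FPKM and the ankyrin ANK3 from 4.88 ± 0.254 to 11 ± 1.77 FPKM.

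The log2 changes of neighbouring genes had a Spearman correlation of 0.3566, against at most 0.0235 in 1000 shuffles of gene order. This describes the shift along chromosomes and not its cause, and a copy number difference between the derivatives stays open as a hypothesis, as does any other regional cause. A scaling factor per library moves all chromosomes about alike, so scaling could not set them apart. After quantile normalization the medians of chromosomes 13 and 10 still differed by 0.8975. GC content, length and level did not account for the shift either, as the chromosome 10 median was -0.4796 after those trends were removed. The design gives the loss of HOTAIR as the biological explanation, and it could not be weighed because HOTAIR was at the limit of detection (exact permutation p = 0.4). Derivative and hairpin coincide in this design, so a difference between derivatives cannot be told from an effect of the hairpin.

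The lower levels of cholesterol synthesis and inflammatory genes could have followed from segment shifts, and regional centring did not remove them. A scaling factor per library moves all genes about alike, and the median log2 change of all genes tested was -0.027. Scaling could therefore not set these lists apart from other genes, and quantile normalization was no separate test of it. After regional centring the list medians were -0.55987 and -0.82726, and after quantile normalization they were -0.62466 and -0.99518. Regional centring removed the shared shifts of neighbours only in part. Their correlation was still 0.0934 after it, above the 0.0235 of the shuffles, so shifts over few genes are not excluded. Whether the loss of HOTAIR was the cause was not tested.

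Short RNA genes lead the largest changes, and a candidate explanation is a few fragments on short genes. Of the 10 genes under 200 bp among the 10 largest rises and 10 largest falls, 8 had values at whole multiples from 1 to 5 of a common unit once library depth was divided out. None of 265 reassignments of the relative depths that moved every library gave such a gene (highest 0). If the unit is 1 fragment, which the values do not show by themselves, these 8 genes rest on 5 fragments or fewer per library, and SNORD27 and RF02220 are not covered. No biological explanation was tested.

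The 6 libraries can be split into 3 and 3 in only 10 ways, too few for a share under 0.05. The real split gave 3797 genes, 8 lists and 12 chromosomes, where the highest of the others gave 12, 6 and 10, so 1 of the 10 splits gave counts that large.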
